A study of Homo sapiens with 43 samples.

How the data were processed

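RNA sequencing counts of 16 libraries were used, 8 from HEK293 and 8 from HK-2 cells. Per the labels, cells were infected with virus carrying Flag-tagged ENL, selected with 10 ug/ml blasticidin and harvested for RNA 4 days after infection, with 2 biological replicates per condition. Libraries were made with the TruSeq RNA v2 kit, which keeps no strand information, and sequenced as read pairs. Whether the replicates of a condition came from separate infections or from the same infected culture is not stated there. The p-values below measure the spread between these samples. If the replicates of a condition shared an infection, that spread leaves out differences between infections. The labels do not say that libraries with the same replicate letter were made together. The 27 chromatin immunoprecipitation samples were not analysed here.

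The deposited values were whole-number counts per Ensembl gene, not normalised, 1 library per table, with no summary lines of the counting tool. Per the submitters' processing notes, the tools of the series included TopHat2 and HTSeq, reads were placed on the hg19 build, and no role, strand setting or rule for reads with several placements was given. Each table held 63677 gene identifiers, of which 52181 were matched to a table of gene names and 39699 had a symbol, carrying 97.62% of counts. A symbol shared by several identifiers was kept on the one with most counts, and the others, 896 identifiers, were kept under their own name. No count fell on mitochondrially encoded genes (0 in every library), so that list was listed at 0 and not tested. Genes that overlap on opposite strands can share reads in unstranded counts, as can close copies such as the KRTAP2 genes, depending on the rule for several placements. Their separate values are uncertain.

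Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For each line, genes were kept by edgeR's filterByExpr over the 4 groups (minimum count 10, minimum total 15), libraries were scaled by TMM (factors between 0.97 and 1.011), and all 8 libraries were fitted together with 4 residual degrees of freedom. The biological coefficient of variation was 4.22% in HEK293 and 3.37% in HK-2. Each mutant was compared with WT and with the other mutants of its line by edgeR's quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fit over all 16 libraries (8 groups, 8 residual degrees of freedom) tested the mutant's effect in HK-2 minus that in HEK293. Fold changes are given on the log2 scale with the standard error of the fit after ±, and group means of CPM with the SD of 2 libraries. The replicates of a group differed by more than counting error (chi-square per degree of freedom between 3.71 and 8.61), so no library was a copy of the other in its group.

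The 33 gene lists were HOXA, HOXB, HOXC and HOXD clusters, HOX antisense and intergenic RNAs, other developmental transcription factors, nephron progenitor, renal stroma progenitor and mature proximal tubule genes, WNT pathway, super elongation complex and partners, MLL-rearranged leukaemia targets, Polycomb group, cell cycle, MYC family and ribosome biogenesis, interferon-stimulated, inflammatory, AP-1 and immediate early, p53 targets, integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, hypoxia and glycolysis, epithelial, squamous, mesenchymal, extracellular matrix, neuronal, endothelial, haematopoietic, histone, mitochondrially encoded and ribosomal protein genes. Of their members, 24 were matched through an older symbol and 13 were not matched, and of 22 histone genes 16 were. Camera, 2-sided, compared each list with all other genes at a preset correlation of 0.01 between genes, adjusted over all lists and the 6 comparisons with WT. Camera with an estimated correlation and fry were run beside it. Lists share some members.

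Named genes followed a rule. MLLT1 came first, then for each comparison with WT the 8 highest and 8 lowest log2 fold changes among genes past the threshold whose 2 mutant libraries both lay on the same side of both WT libraries and whose mean log2 CPM was at least 1, and up to 3 changed members of each list. For other comparisons the 4 highest and 4 lowest were eligible. From this pool the text took mostly genes whose call did not end when 1 library was left out, a preference set after the values were seen and not part of the rule. HOX genes and list members that did not pass are given by value, and list members named for 1 mutant are mostly given for all 3. Single values of 2 list members are not reported here.

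The comparisons, tests, threshold, lists, naming rule and alternatives were fixed before the data were examined. Tests of the lists between lines and of the explanations in the closing section were added afterwards. Alternatives were RLE and upper-quartile scaling, no low-count filter, DESeq2, limma-voom, a fit of the 4 libraries compared or of all 16, the replicate letter as a block, each library left out in turn, an adjusted p of 0.01 and a log2 fold change of at least 1. Shared calls were set beside the number for independent lists and beside 20 simulations of unchanged groups. The pipeline was tested on simulated data of 2 libraries a group with 50 changed genes per size. It recovered 54% of 1.25-fold changes in HEK293 and 74% in HK-2, 90% and 96% of 1.5-fold changes and 98% of 2-fold changes in both. There were 11 false calls in each line. The changed genes had a mean CPM over 1, changed with T1 alone and were far fewer than the genes called in the real data. These rates therefore do not carry over to the real lists of calls.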

Results

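RNA was measured in human cells that carried an introduced, Flag-tagged copy of wild-type (WT) ENL or of 1 of 3 mutants first found in Wilms tumour, a kidney cancer of childhood. ENL, encoded by MLLT1, is a chromatin reader that binds acylated histones through its YEATS domain and works with the machinery of transcription elongation. Per the labels, T1 carries a short insertion, and T2 and T3 carry replacements of a few neighbouring residues. The hosts were HEK293, an embryonic kidney line, and HK-2, an immortalised line of adult proximal tubule. Each line had 4 groups (WT, T1, T2 and T3) of 2 libraries, 16 libraries in all, with RNA collected 4 days after infection. Library totals ranged from 8.41e+07 to 1.03e+08 counts. The title of the series calls the mutations gain-of-function, and the comparisons asked which transcripts differed between each mutant and WT in the same line, between mutants, and between lines. The remaining 27 samples of the series are chromatin immunoprecipitation libraries and were not analysed here.

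MLLT1, the gene of ENL, was read first in every library. In HEK293 it stood at 222 ± 2.2 CPM (counts scaled to the size of the library; SD, n = 2) with WT, and its log2 fold change was 0.42 ± 0.0363 (SE) with T1, 0.53 ± 0.0363 with T2 and 0.35 ± 0.0363 with T3. HK-2 held more, 836 ± 4.7 CPM with WT, and the changes there were 0.46 ± 0.0214, 0.36 ± 0.0214 and 0.29 ± 0.0214. Every mutant library lay above both WT libraries of its line, and the adjusted p from edgeR's quasi-likelihood test was at most 1.34e-06. Counts of the introduced and the endogenous MLLT1 are pooled in these values, so they do not give the amount of either copy. The higher MLLT1 count therefore accompanied every mutant in the comparisons with WT.

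**Figure D1:**
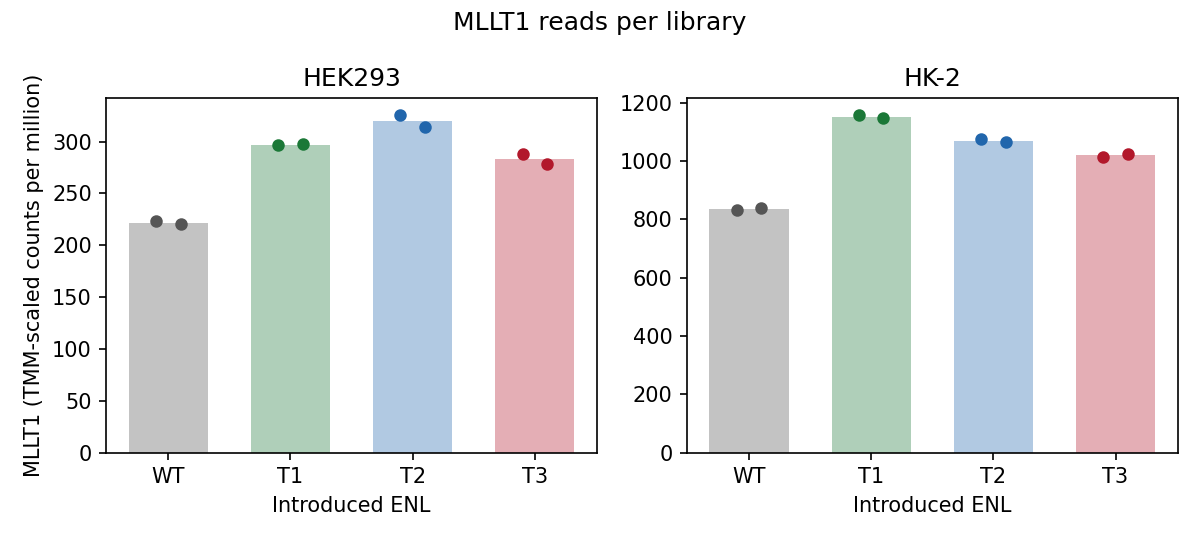
MLLT1 in TMM-scaled CPM (vertical axis) for each introduced form of ENL (horizontal axis) in HEK293 and HK-2; points are the 2 libraries of a group and bars their mean. WT libraries reached 223.4 CPM in HEK293 and 839.5 CPM in HK-2, and the lowest mutant libraries 278.4 and 1016 CPM.

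In HEK293 with T1, RNAs from the HOXA13 end of the HOXA cluster were raised, together with ENSG00000253508, a gene with no symbol in the name table. HOXA13, a limb and urogenital patterning factor, rose from 32.2 ± 2.3 to 176 ± 9 CPM (SD, n = 2), a log2 fold change of 2.45 ± 0.051 (adjusted p = 4.55e-17). HOTTIP, a noncoding RNA transcribed beside HOXA13, rose by 2.29 ± 0.168 and ENSG00000253508 by 3.31 ± 0.139. OR51E2, of the olfactory receptor family, rose by 2.16 ± 0.144, ITGA8, an integrin subunit of kidney mesenchyme, by 1.86 ± 0.0836, and COL17A1, a hemidesmosomal collagen, by 1.74 ± 0.142. Among the lowest were CHAC1, a glutathione-degrading enzyme (-2.08 ± 0.125), SLC7A11, the cystine importer (-2.03 ± 0.134), and STC2, a secreted glycoprotein (-1.89 ± 0.0784). SLC7A5, a leucine transporter, ASNS, which makes asparagine, and DDIT4, an inhibitor of mTORC1, fell too (-1.27, -1.20 and -1.26). Of 23385 genes tested, 4306 passed an adjusted p of 0.05, 2114 higher and 2192 lower, of which 159 and 37 changed at least 2-fold. The count was 2684 without WT replicate A and 2296 without T1 replicate A.

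With T2 in HEK293, HOXA13 rose to 140 ± 3.8 CPM (SD, n = 2), by 2.12 ± 0.0508 on the log2 scale (adjusted p = 6.33e-16). HOXA11, its neighbour in the cluster, rose by 1.33 ± 0.046 and PHACTR1, a regulator of actin and protein phosphatase 1, by 1.52 ± 0.14. OR51E2 (1.999 ± 0.145) and ITGA8 (1.803 ± 0.0839) rose too. CHAC1, SLC7A11 and STC2 fell again, with -1.78 ± 0.123, -1.76 ± 0.132 and -1.74 ± 0.0779. KRT17, a keratin of stratified epithelia, fell (-1.28 ± 0.0908), as did ANKRD1, a nuclear cofactor of muscle and a target of YAP signalling (-1.33 ± 0.126). In all, 3999 of 23385 genes passed, 2004 higher and 1995 lower, with 126 and 57 changed at least 2-fold. Leaving out WT replicate A gave 2333 genes, and leaving out T2 replicate B gave 2610.

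With T3 in HEK293, OR51E2 (2.01 ± 0.145), ITGA8 (1.95 ± 0.0838) and HOXA13 (1.95 ± 0.0508, adjusted p = 3.34e-15) were among the highest log2 fold changes. MME, the ectopeptidase neprilysin of the tubule brush border, rose by 1.47 ± 0.127 and ADGRF5, an adhesion receptor, by 1.42 ± 0.137. ANKRD1 fell from 34.1 ± 6.2 to 11.4 ± 0.66 CPM (SD, n = 2), a change of -1.57 ± 0.129, and CCN2, a matricellular target of the same YAP pathway, by -1.48 ± 0.118. CHAC1 (-1.51 ± 0.121), SLC7A11 (-1.44 ± 0.13) and the actin-like ACTBL2 (-1.31 ± 0.0834) were also lower. Among 23385 genes, 4094 passed, 2031 higher and 2063 lower, and 157 and 43 of these changed at least 2-fold. That count was 2521 without WT replicate A, 2471 without T3 replicate A and 2273 without T3 replicate B.

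The genes of the HOX clusters pattern the body axis, and of the 4 clusters HOXA alone held with an estimated correlation in HEK293. Numbers for T1, T2 and T3 are given in that order for every gene list, counts and p separated by slashes. Of 11 HOXA genes tested, 9 in each mutant rose and 0 fell (9/9/10 adjusted over the list alone), with median log2 fold changes of 0.75, 0.70 and 0.72 for T1, T2 and T3. HOXA4 (0.23, 0.22 and 0.34) and HOXA7 (0.22, 0.08 and 0.07) were the members that did not pass. The HOXA list passed camera, a test of a list against all other genes, with the preset and with an estimated correlation (adjusted p = 0.00237 in each mutant with an estimated correlation). Of 15 HOX antisense and intergenic RNAs, 9/8/10 rose (10/12/10 adjusted over the list alone), among them HOTAIR (2.10, 1.53 and 1.60) and HOXA11-AS (1.87, 1.81 and 1.65), and the list passed (adjusted p = 0.0238/0.0246/0.0246 with an estimated correlation). Reads of these RNAs and of genes on the other strand cannot be told apart in an unstranded library, so their separate values are uncertain. HOXB had 5/4/6 of 9 genes higher and 1 in each mutant lower (adjusted over the list alone, 6/4/6 higher and 1 in each mutant lower), led by HOXB5 (0.80, 0.55 and 0.57). HOXC had 5 in each mutant of 8 higher and 1 lower in T1 (adjusted over the list alone, 5 in each mutant higher and 1/1/0 lower), led by HOXC11 (1.23, 0.93 and 1.04). In HOXD, 5/4/4 of 9 genes rose and 0 fell, with the same numbers adjusted over the list alone; HOXD10 changed by 0.45, 0.34 and 0.32. These last 3 clusters passed camera with the preset correlation but not with an estimated one, where adjusted p = 0.104/0.156/0.115 with an estimated correlation for HOXB, 0.118/0.134/0.134 for HOXC and 0.115/0.159/0.189 for HOXD. Without WT replicate A the preset adjusted p of HOXB in T2 was 0.0515.

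**Figure D2:**
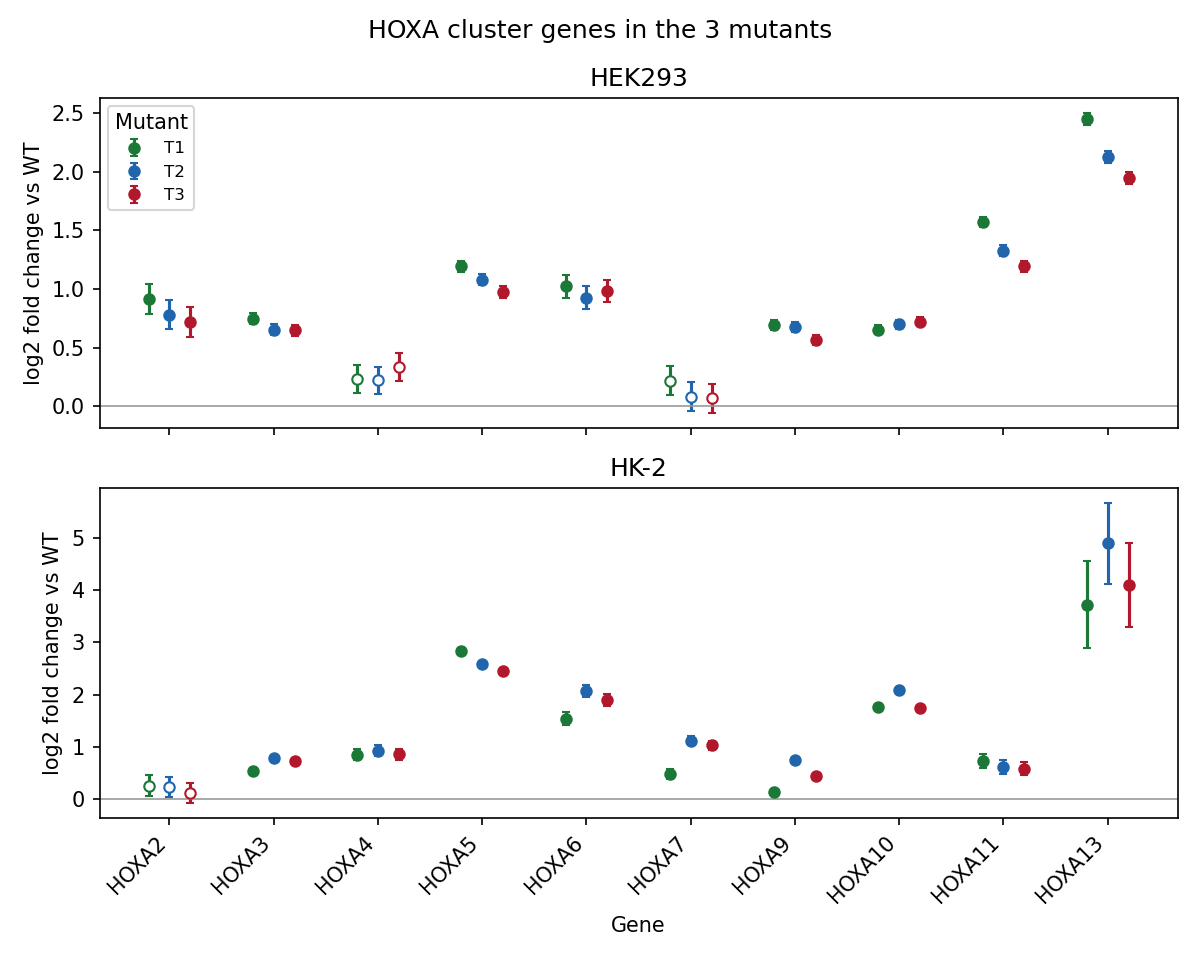
Log2 fold change against WT (vertical axis) of 10 HOXA genes (horizontal axis) for T1, T2 and T3 in HEK293 and HK-2; points are estimates from 2 libraries a group, bars are SE, and open points did not pass an adjusted p of 0.05. HOXA13 was highest in HEK293 (2.45, 2.12 and 1.95), and in HK-2, where HOXA13 was near the detection floor, HOXA5 was highest of the well-counted genes (2.84, 2.60 and 2.45).

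Genes of the integrated stress response, the ATF4 programme for amino acid shortage and misfolded protein, fell together in HEK293. Of 30 members tested, 27/28/27 fell and 0 rose (27/28/27 lower and 0/1/0 higher adjusted over the list alone). Median log2 fold changes were -0.63, -0.65 and -0.52, and the list passed camera (adjusted p = 0.0351/0.0351/0.0449 with an estimated correlation). STC2 changed by -1.89, -1.74 and -1.44 and SLC7A11 by -2.03, -1.76 and -1.44. The WT libraries themselves differed over this list: WT replicate B was higher than replicate A in 29 of 30 members, by a median of 0.206 on the log2 scale, against -0.004 over all genes. In the list of endoplasmic reticulum chaperones and stress genes, 3 in each mutant of 19 rose and 3 in each mutant fell (7/3/3 and 3 in each mutant adjusted over the list alone), with XBP1, a transcription factor of the unfolded protein response, at -0.58, -0.60 and -0.59, and camera made no call (adjusted p = 0.645/0.989/0.975). The MYC family and ribosome biogenesis list had 25/25/26 of 29 members lower and 0/0/1 higher (26 in each mutant and 1 in each mutant adjusted over the list alone), with MYC at -0.89, -0.82 and -0.79 and RRP12, a ribosome assembly factor, at -0.50, -0.56 and -0.54. Its call with the preset correlation was lost with an estimated one (adjusted p = 0.134/0.136/0.118 with an estimated correlation).

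Cytosolic ribosomal protein genes were lower by small amounts in HEK293, with 19/14/8 of 35 down and 1/1/0 up (22/17/10 and 1/1/0 adjusted over the list alone) and medians of -0.11, -0.08 and -0.05. The call was lost with an estimated correlation (adjusted p = 0.342/0.45/0.547 with an estimated correlation), and in T3 it was also lost without WT replicate A (adjusted p = 0.117). For hypoxia and glycolysis, 9 in each mutant of 26 fell and 1 in each mutant rose (10/10/11 and 1 in each mutant adjusted over the list alone), with the angiogenic factor VEGFA at -0.93, -0.83 and -0.70 (adjusted p = 0.208/0.21/0.159 with an estimated correlation). AP-1 and immediate early genes had 10/12/11 of 33 lower and 4/4/2 higher (12/14/13 and 5/7/4 adjusted over the list alone), with CCN2 at -0.94, -1.25 and -1.48 and the phosphatase DUSP1 at -0.71, -0.80 and -0.79 (adjusted p = 0.209/0.201/0.118 with an estimated correlation). With the preset correlation, camera had called both lists as lower (adjusted p = 0.00245/0.00263/0.000221 for hypoxia and 0.00288/0.00243/7.83e-06 for AP-1). These calls were lost with an estimated correlation. In cell cycle and proliferation, 11/7/3 of 41 fell and 2/5/5 rose (12/7/6 and 2/5/5 adjusted over the list alone). Its T1 call (adjusted p = 0.0304) was lost with an estimated correlation (adjusted p = 0.16 with an estimated correlation), without WT replicate B (0.0575) and without T1 replicate B (0.0689); TYMS, thymidylate synthase, stood at 0.27, 0.33 and 0.27.

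Matrix genes went up in HEK293. Of 33 collagens and laminins, 21/19/20 rose and 0/1/2 fell (22/21/21 and 0/2/2 adjusted over the list alone), and the list passed camera (adjusted p = 0.017/0.0185/0.0182 with an estimated correlation). COL3A1, a fibrillar collagen of stroma, went from 0.84 ± 0.093 CPM with WT to 3.5 ± 0.045 with T1 (SD, n = 2), with log2 fold changes of 2.05, 1.82 and 1.88, and COL21A1 changed by 1.08, 1.08 and 1.11. In the WNT pathway list, 12/12/13 of 28 rose and 1 in each mutant fell (13/13/14 and 1 in each mutant adjusted over the list alone), and this list passed (adjusted p = 0.0276 in each mutant with an estimated correlation). RSPO3, a secreted enhancer of WNT signalling, changed by 2.69, 2.13 and 2.50 and the ligand WNT5A by 1.06, 0.94 and 1.01. Renal stroma progenitor genes had 4/3/5 of 13 higher and 0 lower (5/5/8 adjusted over the list alone), a call lost with an estimated correlation (adjusted p = 0.11/0.116/0.0746 with an estimated correlation). Mesenchymal transition genes had 9/9/7 of 31 higher and 4/5/7 lower (9/10/10 and 4/8/7 adjusted over the list alone), with smooth muscle actin ACTA2 at 0.74, 0.59 and 0.80, and no call (adjusted p = 0.0547/0.563/0.655).

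Among kidney lists in HEK293, nephron progenitor genes had 7/7/6 of 30 higher and 2/2/1 lower, with the same numbers adjusted over the list alone. That call, on a list that holds ITGA8, was lost with an estimated correlation (adjusted p = 0.215/0.208/0.208 with an estimated correlation). Mature proximal tubule genes had 4/4/7 of 22 higher and 1 in each mutant lower (5/4/7 and 1 in each mutant adjusted over the list alone), with MME at 1.66, 1.30 and 1.47 and the secreted peroxidase GPX3 at 0.76, 0.78 and 0.74. That call was lost with an estimated correlation (adjusted p = 0.172/0.211/0.16 with an estimated correlation) and, in T2, without WT replicate A (adjusted p = 0.0531). The developmental transcription factors outside HOX had 15/15/11 of 54 higher and 3/2/2 lower (17/17/16 and 3/2/3 adjusted over the list alone), with SOX5 at 0.40, 0.44 and 0.44 (adjusted p = 0.118/0.116/0.137 with an estimated correlation). Of p53 targets, 16/16/17 of 24 rose and 1 in each mutant fell (18/17/18 and 1 in each mutant adjusted over the list alone), with SPATA18, which acts on mitochondria, at 0.70, 0.65 and 0.65 and the quinone oxidoreductase TP53I3 at 0.67, 0.54 and 0.63 (adjusted p = 0.149/0.116/0.116 with an estimated correlation). Of cholesterol synthesis genes, 9 in each mutant of 25 rose and 1/2/2 fell (10/11/9 and 3/2/2 adjusted over the list alone). The sterol reductase TM7SF2 stood at 0.77, 0.73 and 0.74 (adjusted p of the list = 0.303/0.226/0.255 with an estimated correlation). With the preset correlation, camera had called these developmental factors, p53 targets and cholesterol genes as higher in every mutant (adjusted p at most 0.00658). The p53 list was lowest (adjusted p = 8.25e-13/8.39e-18/1.36e-17). All of these calls were lost with an estimated correlation.

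Interferon-stimulated genes in HEK293 had 8/8/10 of 41 higher and 1 in each mutant lower (10/8/10 and 1/2/1 adjusted over the list alone), and camera's call was lost with an estimated correlation (adjusted p = 0.415/0.409/0.334 with an estimated correlation). It was also lost in T1 without WT replicate A (0.0925) or T1 replicate A (0.0695), and in T2 without WT replicate A (0.0859) or T2 replicate B (0.135). Replication-dependent histone genes, of which 16 of 22 could be matched to an identifier, had 2/3/2 of 15 higher and 0 lower (3/3/2 adjusted over the list alone), with H2AC6 at 0.50, 0.50 and 0.51. That call was lost with an estimated correlation (adjusted p = 0.172/0.172/0.16 with an estimated correlation). Without WT replicate B the preset adjusted p was 0.0828 in T1, 0.0883 in T2 and 0.0687 in T3; without WT replicate A it was 0.0645 in T1 and 0.0674 in T2, and without replicate A of the mutant it was 0.127, 0.0989 and 0.0584. With the replicate letter as a block it was 0.0575 in T1 and in T2.

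Camera made no call in HEK293 for the super elongation complex and its partners, where 5/6/4 of 35 rose and 3/3/5 fell (5/6/5 and 4/4/5 adjusted over the list alone), nor for MLL-rearranged leukaemia targets (2/3/4 of 22 up, 7 in each mutant down; 2/3/6 and 7 in each mutant adjusted over the list alone), which include MYC. MLLT1 itself belongs to the super elongation list and was among its higher members with each mutant. Polycomb genes had 4/4/5 of 23 up and 3/2/3 down (4/4/5 and 6/3/4 adjusted over the list alone). Camera also made no call for markers of other cell types or for inflammatory genes. Endothelial markers had 1/1/2 of 10 up and 0 down, with the same numbers adjusted over the list alone and FLT1, a VEGF receptor, at 0.72, 0.48 and 0.47. Epithelial markers had 4/3/3 of 28 up and 5/5/6 down (6/4/5 and 5/6/6 adjusted over the list alone). Squamous keratinocyte markers had 1 in each mutant of 11 up and 1/2/1 down, with the same numbers adjusted over the list alone and KRT17 at -1.01, -1.28 and -1.33. Neuronal markers had 2/1/3 of 25 up and 3 in each mutant down (3/1/4 and 4/3/4 adjusted over the list alone), with the neurofilament NEFM at -0.44, -0.35 and -0.34. Haematopoietic markers had 0/0/1 of 12 up and 1 in each mutant down (0/0/2 and 1 in each mutant adjusted over the list alone), and of 25 inflammatory genes 0 in each mutant rose and 0/0/1 fell (0 in each mutant and 0 in each mutant adjusted over the list alone).

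In HK-2 with T1, HOXA5, a patterning factor from the middle of the HOXA cluster, rose from 11.9 ± 0.36 to 85.5 ± 5.5 CPM (SD, n = 2), a log2 fold change of 2.84 ± 0.0496 (adjusted p = 3e-23). HOXA10 rose by 1.77 ± 0.0423 and SKAP2, an adaptor protein, by 1.82 ± 0.0324. Outside the cluster, CLSTN2, a calsyntenin, rose by 1.65 ± 0.0619, DDIT4L, a relative of DDIT4, by 1.61 ± 0.0684 and the cytokine TNFSF15 by 1.60 ± 0.158. The growth factor AREG, a ligand of the EGF receptor, fell from 120 ± 2.4 to 53.6 ± 0.6 CPM, with -1.17 ± 0.0355, and SHOC1, known from meiosis, changed by -1.32 ± 0.149. AREG shares its values with ENSG00000205595 (-1.17), and the keratin-associated KRTAP2-3 (-1.17 ± 0.0563) has near-identical copies, so both are uncertain as single genes. In total 6648 of 21514 genes passed, 3395 higher and 3253 lower, with 324 and 72 changed at least 2-fold.

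With T2 in HK-2, HOXA5 (2.60 ± 0.0499, adjusted p = 3.75e-22), HOXA10 (2.08 ± 0.0422) and HOXA6 (2.07 ± 0.12) were among the highest log2 fold changes. DDIT4L rose by 1.75 ± 0.0683, the secreted serine protease HTRA1 by 1.71 ± 0.14 and SKAP2 by 1.63 ± 0.0324. SHOC1 (-1.36 ± 0.15), AREG (-1.01 ± 0.0354) and DLEU2, the noncoding host of a microRNA cluster (-0.96 ± 0.128), were lower. The genes past the threshold numbered 5616, 2943 higher and 2673 lower, and 211 and 59 changed at least 2-fold.

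With T3 in HK-2, HOXA5 rose to 65.3 ± 0.78 CPM (SD, n = 2), by 2.45 ± 0.05 (adjusted p = 7.37e-22), HOXA6 by 1.89 ± 0.12 and HOXA10 by 1.74 ± 0.0423. SKAP2 (1.59 ± 0.0323) and FAM89B (1.43 ± 0.102) rose as well. BMI1, a subunit of Polycomb repressive complex 1, fell (-1.14 ± 0.0802), and so did EGR1, an immediate early transcription factor (-0.95 ± 0.0475), and CARMIL2, an actin regulator (-0.88 ± 0.147). Here 4669 genes passed, 2522 higher and 2147 lower, with 172 and 58 changed at least 2-fold. The count was 3000 without T3 replicate A and 3088 without T3 replicate C. A fit of all 16 libraries moved the split in HK-2 to 3522 higher and 2375 lower for T1, 2859 and 2047 for T2 and 2612 and 1350 for T3.

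The HOX lists split by cluster in HK-2. Of 11 HOXA genes, 10 in each mutant rose and 0 fell, with the same numbers adjusted over the list alone, and the medians were 0.85, 0.93 and 1.03; HOXA2 (0.26, 0.23 and 0.11) did not pass. The list passed camera (adjusted p = 0.00481/0.00237/0.00238 with an estimated correlation). HOXA13 was near the floor, at 0.0231 ± 0.033 CPM with WT (0 and 0.0463 in the libraries) and 0.326 ± 0.26, 0.73 ± 0.18 and 0.419 ± 0.26 CPM with T1, T2 and T3. Its fitted log2 fold changes of 3.73, 4.90 and 4.11 became 7.91, 9.08 and 8.29 without WT replicate B, and the T1 call was lost without T1 replicate B (2.53). Of 9 HOXB genes, 7 in each mutant rose and 0/1/0 fell (8/7/7 and 0/1/1 adjusted over the list alone), with HOXB8 at 0.86, 0.92 and 0.99 and HOXB2 at 0.48, 0.75 and 0.68, and this list passed (adjusted p = 0.0413/0.0366/0.0263 with an estimated correlation). HOX antisense and intergenic RNAs had 4 in each mutant of 12 higher and 2/1/0 lower (4 in each mutant and 2/1/2 adjusted over the list alone), led by HOXA-AS3 (2.92, 2.66 and 2.56) and HOTAIRM1 (2.09, 2.05 and 2.04). This list passed as higher (adjusted p = 0.0428/0.0351/0.0363 with an estimated correlation), although its median was negative in T3 (0.19, 0.16 and -0.17). HOXC, with 0/0/1 of 7 higher and 1/0/0 lower, and HOXD, with 0 of 7 higher and 0/1/1 lower, were not called by camera. The numbers adjusted over the list alone were the same. Fry called HOXD as lower (adjusted p = 0.0162/0.0142/0.00813 by fry).

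Cholesterol synthesis and chaperone genes rose in HK-2. Of 25 cholesterol synthesis genes, 24/24/22 rose and 0 fell (24/24/23 adjusted over the list alone), with medians of 0.35, 0.27 and 0.25, MVD of the mevalonate pathway at 0.56, 0.49 and 0.41 and TM7SF2 at 0.61, 0.48 and 0.41. Of 19 endoplasmic reticulum chaperones, 17/14/13 rose and 0 fell (17 in each mutant adjusted over the list alone), with the disulfide isomerase PDIA4 at 0.51, 0.42 and 0.38. Both lists passed camera (adjusted p = 0.0263/0.0308/0.0308 for cholesterol and 0.0238/0.0246/0.026 for chaperones with an estimated correlation). Integrated stress response genes had 15/14/10 of 29 higher and 5/6/7 lower (15/14/12 and 5/6/7 adjusted over the list alone), with CHAC1 at 0.87, 0.72 and 0.61. Camera called them in T1 (adjusted p = 0.00413) and T2 (0.00825), not in T3 (0.183), and the calls were lost with an estimated correlation (adjusted p = 0.192 and 0.212 with an estimated correlation).

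Matrix and mesenchymal genes were higher in HK-2. Of 31 collagens and laminins, 24/22/24 rose and 0 fell (24/23/24 adjusted over the list alone), with COL11A1, a fibrillar collagen of cartilage, at 1.35, 0.89 and 0.94. Mesenchymal transition genes had 16/15/12 of 28 higher and 2 in each mutant lower (17/17/13 and 2/2/3 adjusted over the list alone), with the collagen cross-linking enzyme LOX at 0.76, 0.58 and 0.55. Of 11 renal stroma progenitor genes, 3 in each mutant rose and 0/1/0 fell, with the same numbers adjusted over the list alone; DCN and LUM, matrix proteoglycans, changed by 0.87, 1.04 and 0.90 and 0.90, 0.90 and 0.75. The 3 lists passed with an estimated correlation, where adjusted p = 0.0362/0.0363/0.0413 for matrix, 0.0276/0.0308/0.0403 for mesenchymal and 0.0449/0.0351/0.0353 for stroma genes. Nephron progenitor genes had 6/6/5 of 18 higher and 1/1/0 lower (6/6/5 and 2/1/1 adjusted over the list alone), with CRYM at 0.97, 1.21 and 1.00 and the Notch ligand JAG1 at 0.73, 0.77 and 0.71. Mature proximal tubule genes had 8/7/9 of 19 higher and 1/2/1 lower (8/8/9 and 1/2/1 adjusted over the list alone). Epithelial markers had 8/8/9 of 23 higher and 2/4/1 lower (9/10/10 and 2/4/2 adjusted over the list alone). The last 3 lists were called with the preset correlation and lost with an estimated one (adjusted p = 0.153/0.0581/0.092 for nephron, 0.0717/0.134/0.0924 for tubule and 0.118/0.149/0.0785 for epithelial genes with an estimated correlation). Without WT replicate A the preset adjusted p of nephron genes in T1 was 0.0745, and without T2 replicate A that of epithelial genes in T2 was 0.0727.

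Camera called further lists as lower in HK-2 with the preset correlation and not with an estimated one. Of 41 cell cycle genes, 36/28/27 fell and 0 rose (37/28/30 adjusted over the list alone), with CDT1, which licenses replication origins, at -0.49, -0.35 and -0.35 and the mitotic activator CDC20 at -0.39, -0.34 and -0.31. MYC family and ribosome biogenesis genes had 26/24/21 of 28 lower and 0/1/0 higher (26/25/25 and 0/1/0 adjusted over the list alone), with MYC at -0.54, -0.41 and -0.35. Ribosomal protein genes had 18/18/13 of 35 lower and 0 higher (22/18/15 adjusted over the list alone), by medians of -0.07, -0.07 and -0.05, a call lost in T3 with the replicate letter as a block (adjusted p = 0.0607). Polycomb genes had 11/11/9 of 23 lower and 3/2/2 higher (12/14/11 and 3 in each mutant adjusted over the list alone), with BMI1 at -0.73, -0.89 and -1.14 and the histone methyltransferase EZH2 at -0.53, -0.44 and -0.39. MLL-rearranged leukaemia targets had 7/7/6 of 19 lower and 3/2/1 higher, with the same numbers adjusted over the list alone; in T2 their mean was above 0 (0.007) and their median below it (medians of -0.10, -0.11 and -0.05). All of these were called as lower with the preset correlation and lost with an estimated one. There adjusted p = 0.115/0.16/0.163 with an estimated correlation for cell cycle, 0.134/0.159/0.208 for MYC, 0.293/0.28/0.388 for ribosomal protein, 0.0663/0.0718/0.0717 for Polycomb and 0.135/0.149/0.115 for leukaemia target genes.

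Of 40 interferon-stimulated genes in HK-2, 17/11/10 rose and 2/4/4 fell (19/11/12 and 4/5/4 adjusted over the list alone). Camera called this list in T1 (adjusted p = 0.00116) and T3 (0.0199) and lost both with an estimated correlation (adjusted p = 0.0663 and 0.118 with an estimated correlation). AP-1 and immediate early genes had 11/9/11 of 33 lower and 7/6/5 higher (12/11/11 and 7 in each mutant adjusted over the list alone), with EGR1 at -0.59, -0.73 and -0.95; the T3 call (0.00379) was lost with an estimated correlation (adjusted p = 0.276 with an estimated correlation). Hypoxia and glycolysis genes had 12/10/7 of 27 higher and 4/2/4 lower (12/10/8 and 4/2/4 adjusted over the list alone), with the collagen hydroxylase P4HA2 at 0.50, 0.52 and 0.36. Their T2 call (0.0217) was lost with an estimated correlation (adjusted p = 0.543 with an estimated correlation), without WT replicate A (0.268) and without T2 replicate A (0.112).

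Lists with no call by camera in HK-2 still held single changes. WNT pathway genes had 9/7/3 of 23 higher and 3 in each mutant lower (9/7/6 and 4/3/3 adjusted over the list alone), with WNT5A at 0.64, 0.82 and 0.69. The super elongation complex and partners had 2/3/3 of 34 higher and 9/9/5 lower (2/3/3 and 9/10/5 adjusted over the list alone). MLLT1 itself was among the higher members with each mutant, and the elongation factor ELL2 stood at 0.69, 0.50 and 0.55. Of 41 other developmental transcription factors, 7/7/5 rose and 8/4/5 fell (9/7/5 and 9/4/5 adjusted over the list alone), with FOXC1 at 0.53, 0.99 and 0.80. Inflammatory genes had 12/11/10 of 30 higher and 8/7/8 lower (12/11/11 and 8/7/8 adjusted over the list alone), with the collagenase MMP1 at 1.38, 0.42 and 0.64; its T2 call was lost when any library of the line but T2 replicate B was left out (0.43 and 0.40 without WT replicate A or B, 0.41 without T1 replicate A or B or T3 replicate A or C, 0.20 without T2 replicate A). Of 24 p53 targets, 6/6/4 rose and 4/4/1 fell, with the same numbers adjusted over the list alone and the nuclease AEN at -0.38, -0.38 and -0.29. Neuronal markers had 6/5/3 of 16 higher and 2/1/1 lower (6/6/3 and 2/1/1 adjusted over the list alone), with the granin CHGB at 0.83, 0.52 and 0.84. Haematopoietic markers had 4/3/4 of 10 higher and 2/2/3 lower (4 in each mutant and 3 in each mutant adjusted over the list alone), squamous markers 3/1/2 of 8 higher and 0/1/0 lower with the same numbers adjusted over the list alone. Endothelial markers had 1 in each mutant of 9 higher and 2/0/1 lower (1/0/1 and 2/0/1 adjusted over the list alone), and of 12 matched histone genes 1/0/1 fell and 0 rose (0 adjusted over the list alone).

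**Figure D3:**
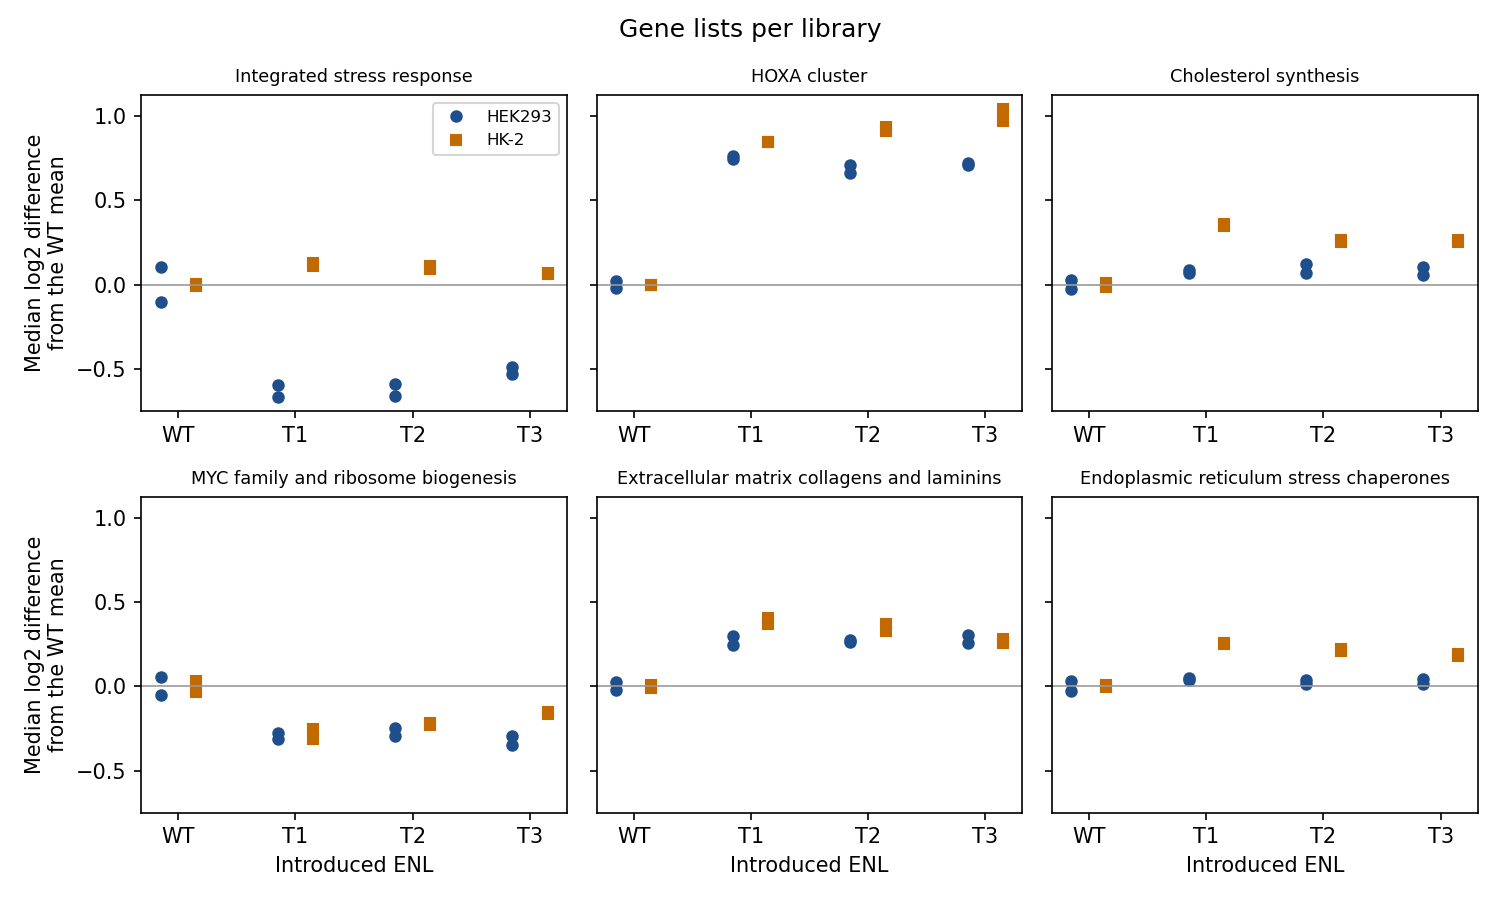
Median log2 difference of each library from the mean of the WT libraries of its line (vertical axis) over 6 gene lists, by introduced ENL (horizontal axis); circles are HEK293 and squares HK-2 libraries, 2 a group. Integrated stress response genes lay below WT in the HEK293 mutants (between -0.49 and -0.66) and not in HK-2, and HOXA genes lay above WT in both lines.

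Mutants differed little from one another in HEK293. Between T1 and T2, HOXA13 (0.33 ± 0.0467, adjusted p = 0.0132) and the cell cycle inhibitor CDKN2B (0.29 ± 0.0376, adjusted p = 0.00518) were higher with T1, the 2 genes past the threshold; HOXA13 was lost without T1 replicate A (0.27) or T2 replicate A (0.30), and CDKN2B without T1 replicate B (0.27) or T2 replicate A (0.30). Between T1 and T3, 20 genes passed, 12 higher with T1, among them HOXA13 (0.51 ± 0.0469, adjusted p = 3.42e-05). That split rested on single libraries, with 22 of 28 higher without T1 replicate A and 9 of 27 without T1 replicate B. Between T2 and T3 edgeR called 0 genes, with 1393 at an unadjusted p under 0.05, and DESeq2 called 11. These small counts moved with single libraries. T1 against T2 gave 6 genes without WT replicate A, 8 without WT replicate B, 5 (2 of them higher with T1) without T1 replicate A, 1 without T1 replicate B and 0 without T2 replicate A. T1 against T3 gave 51 and 57 without WT replicate A or B, 56 and 60 without T2 replicate A or B, and 1 and 4 without T3 replicate A or B. T2 against T3 gave 5 without either T1 replicate A or B, 11 without T2 replicate B and 2 without T3 replicate B.

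In HK-2 more genes passed between mutants. T1 exceeded T2 in MMP1 (0.96 ± 0.139, adjusted p = 0.000119), TNFSF15 (0.89 ± 0.148) and the aldehyde oxidase AOX1 (0.80 ± 0.107), and lay below it in the cytokine LTB (-0.86 ± 0.0685) and MIR205HG, the host of a microRNA (-0.70 ± 0.0511). T1 exceeded T3 in MMP1 (0.74 ± 0.135) and lay below it in LTB (-0.88 ± 0.0681), MIR205HG (-0.72 ± 0.0508) and HOXA7 (-0.55 ± 0.0835, adjusted p = 0.000257). T2 lay below T3 in C11orf68 (-0.39 ± 0.039) and CCDC85B (-0.39 ± 0.0572). The counts were 544 genes between T1 and T2 (288 higher with T1), 589 between T1 and T3 (365 higher with T1) and 73 between T2 and T3 (56 higher with T2). With the replicate letter as a block T1 against T2 gave 566 genes, and the comparisons with T3 rested on T3 replicate A alone. T1 against T2 gave 217 and 259 (123 and 121 higher with T1) without T2 replicate A or B. T1 against T3 gave 872 without T1 replicate A, of which 369 were higher with T1, so the direction of the majority rested on that library, and it gave 280 without T1 replicate B and 167 and 181 without T3 replicate A or C. T2 against T3 gave 21 and 42 without T2 replicate A or B and 22 and 25 without T3 replicate A or C.

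The 3 mutants changed overlapping sets of genes. In HEK293, 1346 genes were higher and 1331 lower in all 3, HOXA13 and CHAC1 among them, and pairs of mutants shared 3257 (T1 and T2), 3029 (T1 and T3) and 2999 (T2 and T3) calls in the same direction and 0 in opposite directions. Independent lists would share 181 higher and 187 lower, 184 and 193, and 174 and 176 genes. Across 14680 genes, which are not independent replicates, log2 fold changes correlated with r = 0.927, 0.892 and 0.904. In 20 simulations of unchanged groups that shared simulated WT libraries, r was 0.501, 0.496 and 0.498. The simulated WT libraries were drawn with the spread within groups, so a state shared by both real WT libraries was not in them. The covariance was 0.0414, 0.0408 and 0.0394 against 0.00363, 0.00362 and 0.00364 simulated. In HK-2, where HOXA5 and SKAP2 were among 1966 genes higher and AREG among 1603 lower in all 3 mutants, pairs shared 4591, 4011 and 3846 calls, with 10, 6 and 1 in opposite directions. Independent lists there would share 464 higher and 404 lower, 398 and 325, and 345 and 267. The correlation was r = 0.887, 0.894 and 0.902 against 0.506, 0.51 and 0.508 simulated, and the covariance 0.0467, 0.0432 and 0.0388 against 0.00307. Part of the excess may come from the shared WT libraries, which were too few to be split between the mutants of a pair.

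Across the lines, each mutant's calls overlapped more than independent lists would. With T1, 863 genes were higher and 1119 lower in both lines (305 and 342 for independent lists of 20195 genes tested in both), with T2 719 and 945 (251 and 256), and with T3 653 and 786 (216 and 212). Odds ratios from Fisher's exact test were 5.57, 5.17 and 5.35 for higher and 8.27, 9.13 and 8.03 for lower genes. The p-values tested for more overlap alone, and the largest of the 6 adjusted p was 4.93e-178. In opposite directions there were 289, 238 and 206 genes, among them CHAC1. Across 12794 genes, which are not independent replicates, the changes in the lines correlated with r = 0.414, 0.388 and 0.372 (Spearman's rho 0.439, 0.415 and 0.39). In all 6 comparisons 430 genes were higher, HOXA5 and MLLT1 among them, and 551 lower, with MYC among them.

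The difference between the lines was tested directly as the mutant's effect in HK-2 minus its effect in HEK293. CHAC1 differed with each mutant, by 2.98 ± 0.177, 2.51 ± 0.176 and 2.14 ± 0.175 (adjusted p at most 4.45e-09), since it was higher in HK-2 and lower in HEK293. SLC7A11 (2.63 ± 0.169) and STC2 (2.07 ± 0.0965) differed the same way with T1, and ANKRD1 (2.37 ± 0.168) and CPA4, a carboxypeptidase (1.96 ± 0.152), with T3. RSPO3 had the lower effect in HK-2 with T1 (-2.35 ± 0.24) and T3 (-2.27 ± 0.244), AREG with T1 (-1.54 ± 0.172) and CYRIA, a regulator of RAC1, with T2 (-1.27 ± 0.109). Of 24844 genes, 2523 differed with T1, 1775 of them (70.4%) with the higher effect in HK-2, 2029 with T2 (1365, 67.3%) and 2070 with T3 (1471, 71.1%). That share rested on the scaling, since RLE factors gave 55.4%, 53.2% and 55.2% and DESeq2 54.4%, 52.4% and 55.3%. The T3 count was 1334 without HEK293 T3 replicate B and 1326 without HK-2 T3 replicate C.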

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

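The gene differences between lines below come from the planned contrast, while the list tests between lines and every test of an explanation were chosen after the results were seen. Of 94 named genes tested, 73 had an effect in HK-2 that differed from the effect in HEK293 with at least 1 mutant. They were named mostly because they changed, so that share does not describe all genes, of which 10.2%, 8.17% and 8.33% differed with T1, T2 and T3. The log2 difference, HK-2 minus HEK293, is given for the mutant with the smallest adjusted p, from 2 libraries a group.

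With T1, the effect was higher in HK-2 for CHAC1 (2.98), SLC7A11 (2.63), MMP1 (2.36), STC2 (2.07), HOTAIRM1 (1.802), HOXA5 (1.67), ASNS (1.67), TNFSF15 (1.42) and FAM89B (1.39). Next came SKAP2 (1.34), SLC7A5 (1.32), CLSTN2 (1.19), AOX1 (0.87), CHGB (0.77), XBP1 (0.72), ELL2 (0.59), DUSP1 (0.53) and LOX (0.51). Smaller differences were those of MVD (0.34) and PDIA4 (0.26). With T1, the effect was lower in HK-2 for ENSG00000253508 (-5.78), HOTAIR (-3.44), LTB (-2.55), RSPO3 (-2.35), SHOC1 (-1.99), AREG (-1.54), ENSG00000205595 (-1.53), CYRIA (-1.34) and CARMIL2 (-1.05). Next came MME (-1.02), HOXA11 (-0.82), TP53I3 (-0.50), WNT5A (-0.40), TYMS (-0.37), EZH2 (-0.37), CDT1 (-0.29) and CDC20 (-0.21). With T2, the effect was higher in HK-2 for HOXA13 (2.79), HTRA1 (1.64), HOXA10 (1.40), HOXA-AS3 (1.38), DDIT4L (1.23), HOXA6 (1.16), HOXA7 (1.05), CRYM (0.96) and VEGFA (0.94). Next came HOXA4 (0.72), DDIT4 (0.72), P4HA2 (0.68), FOXC1 (0.65), LUM (0.64) and JAG1 (0.62). With T2, the effect was lower in HK-2 for KRTAP2-3 (-4.02), GPX3 (-0.45), AEN (-0.41) and MLLT1 (-0.16). With T3, the effect was higher in HK-2 for ANKRD1 (2.37), CPA4 (1.96), CCN2 (1.47), ACTBL2 (1.22), C11orf68 (1.01), HOXB8 (0.98), HOXB2 (0.52), MYC (0.46) and CCDC85B (0.40). Next came RRP12 (0.31). With T3, the effect was lower in HK-2 for HOXA11-AS (-2.24), COL17A1 (-1.79), PHACTR1 (-1.30), BMI1 (-1.11), HOXD10 (-0.61), EGR1 (-0.55) and TM7SF2 (-0.30).

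Some of these differences rested on single libraries or on low counts. KRTAP2-3 and SHOC1 had too few counts to be tested in HEK293 alone, and ENSG00000253508 and HOTAIR in HK-2 alone. Counts of LTB and MMP1 in HEK293 and of HOXA13 and PHACTR1 in HK-2 lay near the floor. Libraries are named below by line, form of ENL and replicate letter. AOX1 was no longer called without HEK293 T1 A (0.68). CCDC85B was no longer called without HEK293 T3 B (0.36) and HK-2 WT A (0.34). CDC20 was no longer called without HEK293 WT B (-0.16), HEK293 T1 B (-0.18) and HK-2 T1 B (-0.19). CRYM was no longer called without HEK293 WT A (0.68), HEK293 T2 A (0.79), HK-2 WT A (0.91) and HK-2 T2 A (0.92). HOTAIR was no longer called without HK-2 WT B (-3.18), and stood at another size without HK-2 T1 B (-8.00). HOXA13 was no longer called without HEK293 WT B (2.71), HEK293 T2 A (2.77), HK-2 WT A (1.82), HK-2 WT B (7.16) and HK-2 T2 A (2.53). KRTAP2-3 was no longer called without HEK293 T2 B (-3.10). MLLT1 was no longer called without HEK293 T2 A (-0.13), HK-2 WT B (-0.15) and HK-2 T2 B (-0.15). MMP1 was no longer called without HEK293 WT A (0.38), HEK293 T1 B (1.82), HK-2 WT A (2.36), HK-2 WT B (2.34), HK-2 T1 A (2.38) and HK-2 T1 B (2.33). PHACTR1 was no longer called without HEK293 WT B (-1.14), HEK293 T3 A (-1.27), HEK293 T3 B (-1.32), HK-2 WT A (-1.09), HK-2 WT B (-1.48), HK-2 T3 A (-1.36) and HK-2 T3 C (-1.24). RRP12 was no longer called without HEK293 WT A (0.26), HEK293 T3 B (0.23), HK-2 WT B (0.27) and HK-2 T3 A (0.29). SHOC1 was no longer called without HEK293 WT A (-2.34), HEK293 WT B (-1.66), HEK293 T1 A (-1.77), HEK293 T1 B (-2.18), HK-2 WT A (-2.09), HK-2 WT B (-1.89), HK-2 T1 A (-1.91) and HK-2 T1 B (-2.07). TM7SF2 was no longer called without HEK293 WT A (-0.22), HEK293 T3 A (-0.26), HK-2 WT B (-0.28) and HK-2 T3 C (-0.24). TP53I3 was no longer called without HEK293 WT A (-0.41), HEK293 T1 A (-0.36), HK-2 WT B (-0.46) and HK-2 T1 B (-0.43). WNT5A was no longer called without HK-2 T1 B (-0.28).

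Each tested list was compared between lines with each mutant, 96 tests in all. In at least 1 mutant, 9 lists held with an estimated correlation. Integrated stress response genes had the higher effect in HK-2, with median differences of 0.69, 0.65 and 0.57 for T1, T2 and T3 (adjusted p = 0.00367, 0.00367 and 0.00847 with an estimated correlation). HOXA genes differed by 0.54, 0.72 and 0.55, HOXB genes by 0.34, 0.35 and 0.32, endoplasmic reticulum chaperones by 0.24, 0.18 and 0.17 and mesenchymal genes by 0.23, 0.29 and 0.27, each with adjusted p at most 0.0316 with an estimated correlation. HOXD genes had the lower effect in HK-2 (-0.42, -0.40 and -0.42), as did Polycomb genes (-0.12, -0.073 and -0.034). Cholesterol synthesis genes held in T1 (0.26, adjusted p = 0.0234 with an estimated correlation) and not in T2 (0.103) or T3 (0.137). WNT pathway genes held as lower in T3 (-0.088, adjusted p = 0.0353 with an estimated correlation), and their median in T1 was above 0 (0.04).

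HOXA genes were higher with every mutant in both lines, and the mutants also had more MLLT1 transcript than WT. Among 66 tests of HOXA genes between mutants, 17 called differences were split, 9 against and 8 with the order of MLLT1. A narrower count, chosen after that one had been seen, took the 12 between mutants that themselves differed in MLLT1, and 8 were higher in the mutant with fewer MLLT1 counts. The other 4 were higher in the mutant with more MLLT1 counts. Those 12 all lay in HK-2, between T1 and either T2 or T3, and HOXA3, HOXA7 and HOXA9 were counted in both pairs. HOXA genes there thus did not all follow the order of the pooled MLLT1 count. The level of the introduced copy is not known, so the test cannot tell whether that level set the order among mutants. In HEK293 no difference in MLLT1 between mutants passed, so the order there was not tested. Reads from overlapping genes were argued against in HEK293 by 4 HOXA genes whose RefSeq spans overlap no other gene. All 4 were called higher there with the 3 mutants. In HK-2, 3 of them were called, and HOXA13, near the floor there, was among these. The counts are per Ensembl gene on hg19, and overlaps in that annotation were not checked. The step from WT to mutant cannot be told apart from a higher MLLT1 level, since every mutant library exceeded every WT library of its line in MLLT1, by at least 0.275 on the log2 scale. The mutation itself, which the design names, stays open as an explanation beside that level, and the data may hold both.

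Integrated stress response genes were lower with every mutant in HEK293 and not in HK-2. A single WT library in another state was argued against, since without either one at least 23 of 30 genes were still called lower in each mutant. Library scaling was argued against as well, the median closest to 0 under RLE or upper-quartile factors being -0.50. A culture state shared by both WT libraries cannot be told apart from an effect of the mutants, since there was no second set of WT cultures, and the WT libraries differed over the list by a median of 0.206. An effect of the mutants in this line may therefore stand beside that culture state, and the libraries do not separate them.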

How the results depend on the processing

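The alternatives below were fixed before the data were examined, and none reversed the direction of a named gene or of a called list. Of 1077 calls of named genes against WT, 807 were not lost with any other scaling, filter, method, fit or left-out library, and 270 were lost with at least 1; the stricter p and fold-change thresholds were applied to counts alone. RLE scaling kept 1076, and the fit of all 16 libraries kept 987. Of 146 calls between mutants 58 were never lost, and of 382 between lines 266. A call with no value under an alternative was counted as not lost. DESeq2 gave no value for 36 calls against WT, 10 between mutants and 4 between lines, and the fit of the 4 libraries compared for 3 against WT. With 1 library left out, the lone library of its group is assumed to vary like the other groups.

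At an adjusted p of 0.01, HEK293 had 2489, 2231 and 2454 genes for T1, T2 and T3, and HK-2 T3 had 3011. With a log2 fold change of at least 1, the counts were 196, 183 and 200 in HEK293 and 396, 270 and 230 in HK-2, and shared calls were 99 (T1 and T2), 1.0e+02 (T1 and T3, 90 higher and 13 lower) and 106 (T2 and T3) in HEK293, 147, 141 and 1.1e+02 (9 of them lower) in HK-2, and 15, 8 and 7 between lines. Fewer genes pass by construction there. Of 115 list calls, an estimated correlation kept 39 (36 higher, 3 lower) and the replicate block lost 3. Fry kept 110 and lost 5. Those lost were interferon-stimulated (T1, T2) and ribosomal protein genes (T2, T3) in HEK293 and hypoxia genes (T2) in HK-2. Fry called 143 list results in all, some of them not called by camera. Among these were WNT pathway genes in HK-2 (higher, adjusted p = 0.00204/0.00201/0.0106 by fry) and endothelial markers in HEK293 (higher, 0.00125/0.00361/0.00177).

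Counts between mutants moved too. Without a low-count filter, HEK293 gave 28 genes for T1 against T2, 202 for T1 against T3 and 91 for T2 against T3, and HK-2 gave 142 for T2 against T3. DESeq2 gave 9, 51 and 11 in HEK293 and 1.1e+02 (83 higher with T2 and 28 lower) for T2 against T3 in HK-2. With the replicate letter as a block there were 7 (T1 against T2) and 49 (T1 against T3) in HEK293, and 217 (T1 against T3) and 32 (T2 against T3) in HK-2, and this replicate block moved no other count by more than 1.5 times. In HK-2 the letter C occurred with T3 alone, so under this block the T3 estimates there rested on T3 replicate A. The letters were not known to pair libraries. Replicate differences correlated by letter between -0.099 and 0.19 in HEK293 and between -0.055 and 0.15 in HK-2. The cause of these moves was not tested.

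With 1 library left out in turn, counts ran from 2296 to 4365 for T1 against WT in HEK293, 2333 to 3937 for T2 against WT in HEK293, 2273 to 4155 for T3 against WT in HEK293 and 0 to 8 for T1 against T2 in HEK293. They ran from 1 to 60 for T1 against T3 in HEK293, 0 to 11 for T2 against T3 in HEK293, 3000 to 4940 for T3 against WT in HK-2 and 217 to 617 for T1 against T2 in HK-2. The range was 167 to 872 for T1 against T3 in HK-2, 21 to 109 for T2 against T3 in HK-2 and 1326 to 1976 for T3 between the lines. The cause of these ranges was not tested.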

Other observations

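The tests of neighbouring genes were chosen after the results were seen. Genes changed at least 2-fold were next to one another along a chromosome more often than in 1000 shuffles of gene order, among them HOXA11 beside HOXA13 in HEK293 with each mutant, and HOXA5 beside HOXA6 in HK-2 with each mutant. In HEK293, 8, 4 and 6 neighbouring pairs changed the same way with T1, T2 and T3, against shuffled means of 0.963, 0.612 and 0.85, and in HK-2 16, 9 and 6 against 3.44, 1.07 and 0.897. The permutation p was at most 0.003, and 0.001 is the smallest that these shuffles can give.

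Reads shared by neighbours that overlap each other were argued against. Pairs whose RefSeq spans do not overlap gave the same numbers, with a permutation p of at most 0.003. Members of a pair can overlap other genes, as HOXA5 and HOXA6 do with 2 each, so reads shared with such genes were not excluded. Reads shared by related copies could explain part of the excess: pairs whose symbols differed in their first 3 letters numbered 3, 2 and 2 in HEK293 and 8, 2 and 2 in HK-2, with a permutation p as high as 0.267 and below 0.05 with T1 in HK-2 alone (0.017). The HOX genes count as related copies in that test, so it does not separate a cluster that moved together from shared reads.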
